A study of Macaca mulatta with 10 samples.

How the data were processed

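RNA from 10 samples of the rhesus macaque ES cell line ORMES6 was measured on Affymetrix rhesus macaque arrays, in 5 groups of 2 arrays taken from the sample titles. Per the labels' protocols, undifferentiated cells grew on mouse embryonic fibroblast feeders, differentiation was induced by co-culture with fibroblast-like cells made from human ES cells, total RNA was treated with DNase, and biotinylated cRNA was prepared from it by the standard Affymetrix protocol. Such arrays read the transcripts of all cells in a sample, so cells carried over from the feeders or the co-culture could add signal where their transcripts match the macaque probes.

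The deposited values are log2 expression values made with RMA per the labels, which give no version. The log base is not stated and was inferred from the values, since the largest range of a probe set over the arrays, 9.51, would be 13.7 in log2 units if the values were natural logs. Each probe set had been centred on its median over the 10 arrays before deposit (0 of the 44294 probe sets had a median beyond 1e-05), so the values give differences between arrays and no absolute level. The 84 control probe sets of the manufacturer were left out, which left 44210 tested probe sets, among them 377 for viral and 22 for reporter sequences. Of all tested probe sets, 22802 were assigned to 1 gene, 316 to several genes and 21092 to none. A gene's value was the mean of its probe sets, which gave 13191 genes, 7438 of them with 1 probe set. Gene names came from the platform annotation, and 22520 of 22815 annotated probe sets were matched to a RefSeq table by gene number, with 0 names changed.

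All 10 arrays were fitted in 1 linear model with a term per group in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation (5 residual degrees of freedom, prior 4.33 and prior standard deviation 0.159). The 6 comparisons were IVDS2, IVDS3, IVDS2-C and IVDS2-P against ES cells, IVDS2-C against IVDS2-P, and IVDS3 against IVDS2. A probe set or gene was called at an adjusted p under 0.05 (Benjamini-Hochberg, over 44210 probe sets or over 13191 genes, within each comparison), and values are given as log2 fold change ± standard error (SE). "Rose" and "fell" are used for called items. The 30 gene lists (675 genes, 474 measured) and the landmark genes were fixed before the data were examined. Lists were tested with camera in limma, two-sided, with the preset correlation between genes of 0.01, adjusted over the 30 lists, and again with the correlation estimated from the data. Some genes stand in several lists. The lists tell cell types apart only as far as their genes do, and "adjusted over the list alone" means adjusted over the measured genes of 1 list.

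Genes are named by a rule: the 8 largest rises and falls among called genes whose arrays do not overlap between the groups, up to 4 called members of each called list in the direction of the list, and 20 landmark genes of pluripotent and liver cells and of fibroblasts, of which 16 were measured. LIN28A, HNF4A, ALB and TTR were not analysed here. The members of a list given as examples are mostly those whose call held whichever array was left out, and genes with a locus number in place of a name are left out. Genes outside this rule are said to be chosen after their values were seen. The position of each array on the axis from periphery to centre was its projection over the probe sets called between IVDS2-C and IVDS2-P, scaled so that the mean of IVDS2-P was 0 and that of IVDS2-C was 1.

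The values differed from the plan in that they were centred. The planned choice of the brightest probe set of a gene was not possible, and the mean of its probe sets, meant as a variation, took its place. For the same reason quantile normalization, a filter on dim probe sets and a variance prior with an intensity trend were not run. Alternatives that were run were centring each array on its median, fitting only the 4 arrays compared, the replicate number as a block, leaving out each array in turn, the most variable probe set of each gene, the estimated correlation for lists, and, for the axis, only probe sets that differ at least 2-fold. List medians are also given within each replicate number, as a measure of spread.

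Simulated data had 100 of 44210 probe sets changed 2-fold and 100 changed 4-fold, far fewer than were called on the arrays. The fit recovered 53% and 93% for IVDS3 against ES and 56% and 90% for IVDS2-C against IVDS2-P, with 3.31% and 3.95% of calls false. These rates need not hold for the arrays. Replicate differences had an SD over probe sets of 0.40 (ES), 0.28 (IVDS2), 0.29 (IVDS2-C), 0.27 (IVDS2-P) and 0.24 (IVDS3).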

Results

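Gene expression was measured with Affymetrix rhesus macaque arrays in ORMES6, an embryonic stem (ES) cell line of the rhesus macaque, before and during differentiation toward liver cells. Differentiation was induced by co-culture with hESdF, fibroblast-like cells made from human ES cells. The 10 arrays form 5 groups of 2 arrays: undifferentiated ES cells, differentiated cells at IVDS2, the central foci of colonies at IVDS2 (IVDS2-C), the peripheral area of such colonies (IVDS2-P), and differentiated cells at IVDS3. The labels do not spell out IVDS, and IVDS2 and IVDS3 are read here as differentiation stages 2 and 3. The series title describes the differentiation as depending on topology. The comparisons therefore asked how each group differed from ES cells, how the colony centre differed from its periphery, and what changed between stages 2 and 3. The few arrays limit the precision. The labels do not say whether the repeats of a condition came from separate cultures, so each p-value measures the spread between these samples, which can be technical.

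IVDS3 was the group that differed from ES cells at the most probe sets. Against ES cells, limma called 3339 of the 44210 tested probe sets in IVDS2-P (2199 higher and 1140 lower), 3851 in IVDS2 (2175 higher and 1676 lower), 9507 in IVDS2-C (5006 higher and 4501 lower) and 16708 in IVDS3 (7900 higher and 8808 lower). The colony centre differed from the periphery at 2582 probe sets, 1700 of them higher in the centre, and IVDS3 differed from IVDS2 at 12639, 6000 of them higher in IVDS3. ES replicate 2 read higher than the other arrays at viral probe sets (median 0.34 on the log2 scale), and without it the counts against ES cells were 1527, 2610, 7804 and 15089. Other single arrays moved a count by more than 1.5 times. For IVDS2-P it was 7423 without ES replicate 1, 1942 without IVDS2-P replicate 1 and 818 without IVDS2-P replicate 2. For IVDS2 it was 2437 without IVDS2 replicate 1 and 1757 without IVDS2 replicate 2, and for IVDS2-C it was 4263 without IVDS2-C replicate 2. The centre and periphery differed at 749 probe sets without IVDS2-C replicate 2, 684 without IVDS2-P replicate 1 and 1277 without IVDS2-P replicate 2. IVDS3 and IVDS2 differed at 8409 without IVDS2 replicate 2 and at 7899 without IVDS3 replicate 1. With only the 4 arrays compared the counts were 1514 (IVDS2-P), 2115 (IVDS2), 5248 (IVDS2-C) and 1685 (centre against periphery). The balance of higher and lower was not stable in 3 comparisons. For IVDS3 against ES cells it turned to 8561 higher and 7499 lower with each array centred on its median. It also turned with only the 4 arrays compared (6745 and 6497) or without IVDS3 replicate 1 (6074 and 5945) or 2 (6306 and 6188). For IVDS3 against IVDS2 it turned to 6514 and 5741 with centred arrays, 5028 and 4699 without IVDS2 replicate 1, and 4290 and 4119 without IVDS2 replicate 2. It was 4224 and 3675 without IVDS3 replicate 1 and 4625 and 4381 without IVDS3 replicate 2. For IVDS2-C against ES cells it was 3800 higher and 4004 lower without ES replicate 2.

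**Figure D1:**
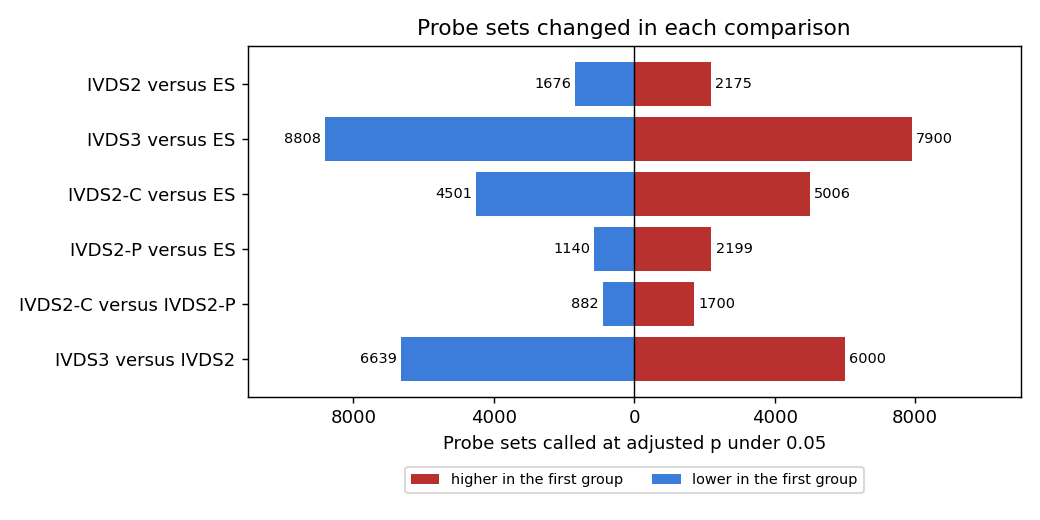
Horizontal bars give the number of probe sets called higher or lower in each of the 6 comparisons, out of 44210 tested. The bars for IVDS3 against ES cells are together the longest (16708 probe sets).

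At stage 2, 9 of 17 members of the trophoblast list, 4 of 9 of the epidermal list and 4 of 19 of the neural ectoderm list had risen over ES cells, and 9 of 19 of the pluripotency list had fallen (adjusted p = 0.147, 0.156, 0.309 and 0.377 with an estimated correlation). The largest rise was in HAPLN1, which ties hyaluronan to proteoglycans in the extracellular matrix (log2 fold change 7.07 ± 0.27 (SE), 134-fold, n = 2 arrays per group, adjusted p = 1.19e-05). Other large rises were those of the scavenger receptor COLEC12 (5.86 ± 0.60), the nuclear receptor NR2F2 (4.73 ± 0.31), ERP27 (4.33 ± 0.21) and the GABA receptor subunit GABRP (4.10 ± 0.23), with adjusted p of at most 0.000594. Among the largest falls were ITM2A (-4.95 ± 0.34), the glycosyltransferase MGAT4C (-3.90 ± 0.22), the interferon-inducible membrane protein IFITM1 (-3.66 ± 0.33) and JAZF1 (-3.25 ± 0.30), with adjusted p of at most 0.000415. GALNT1 (-3.42 ± 0.44), ARHGAP36 (-3.66 ± 0.68) and SPP1 (-3.41 ± 0.78) fell too. The call for ARHGAP36 was lost without IVDS2 replicate 1 (adjusted p = 0.0575), and that for SPP1 without ES replicate 1 (adjusted p = 0.0869), IVDS2 replicate 1 (adjusted p = 0.0907) or IVDS2 replicate 2 (adjusted p = 0.0967).

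In the trophoblast list, 9 of 17 measured members rose (9 adjusted over the list alone) and the other 8 were not called. Its leading members were VGLL1 (4.01 ± 0.29), a cofactor of TEAD factors, and the transcription factors GATA3 (3.50 ± 0.33) and TFAP2A (3.05 ± 0.23). The list median was 1.01, with 1.02 between the replicate 1 arrays and 1.01 between the replicate 2 arrays (camera adjusted p = 1.81e-06, and adjusted p = 0.147 with an estimated correlation). In the epidermal ectoderm list, 4 of 9 measured members rose (5 adjusted over the list alone) and the other 5 were not called. Those that rose included GRHL3 (3.07 ± 0.17), a regulator of the skin barrier, TP63 (2.38 ± 0.14), a master regulator of stratified epithelium, and PERP (1.50 ± 0.25), a desmosome protein. Its median was 0.92, with 0.96 between the replicate 1 arrays and 0.88 between the replicate 2 arrays (camera adjusted p = 1.9e-05, and adjusted p = 0.156 with an estimated correlation), and TP63 and TFAP2A stand in both lists. In the neural ectoderm list, 4 of 19 measured members rose (6 adjusted over the list alone) and the other 15 were not called. Those that rose were LMX1A (3.12 ± 0.22) and PAX3 (2.91 ± 0.20) of the dorsal neural tube and PAX6 (2.92 ± 0.48) and EMX2 (2.49 ± 0.32) of the forebrain (camera adjusted p = 0.000468, and adjusted p = 0.309 with an estimated correlation). In the neural crest list, 7 of 13 measured members rose and 2 fell (7 and 2 adjusted over the list alone). Rises included MSX2 (4.29 ± 0.25), TFAP2B (3.08 ± 0.19) and MSX1 (2.91 ± 0.23) (camera adjusted p = 0.000468, and adjusted p = 0.206 with an estimated correlation).

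In the pluripotency list, 1 of 19 measured members rose and 9 fell (1 and 9 adjusted over the list alone). The falls included the DNA methyltransferase DNMT3B (-2.72 ± 0.37), the nuclear receptor NR5A2 (-2.66 ± 0.24) and SOX2 (-2.06 ± 0.21), each called whichever array was left out. The list median was -0.82, with -0.54 between the replicate 1 arrays and -1.28 between the replicate 2 arrays, and -0.46 without ES replicate 2 (camera adjusted p = 1.35e-05, and adjusted p = 0.377 with an estimated correlation). POU5F1, which encodes OCT4, had a log2 fold change of -3.34 ± 0.79 (adjusted p = 0.0249), and its call was lost without ES replicate 1 (adjusted p = 0.0614), ES replicate 2 (adjusted p = 0.112) or IVDS2 replicate 2 (adjusted p = 0.163). NANOG, measured by a single probe set, rose by 1.04 ± 0.19 (adjusted p = 0.00919), a call lost without IVDS2 replicate 2 (adjusted p = 0.0596). The members of the list that fell numbered 5 without that array.

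Epithelial and signalling genes moved as well. In the epithelial junction list, 7 of 21 measured members rose (8 adjusted over the list alone) and the other 14 were not called. Those that rose included KRT8 (2.14 ± 0.23) and the trafficking protein RAB25 (1.90 ± 0.28) (camera adjusted p = 2.24e-06, and adjusted p = 0.377 with an estimated correlation). In the cholangiocyte list, 4 of 13 measured members rose and 1 fell (8 and 1 adjusted over the list alone). Rises included KRT19 (2.19 ± 0.20) and SOX9 (1.95 ± 0.22) (camera adjusted p = 0.000468, and adjusted p = 0.206 with an estimated correlation). In the BMP and TGF-beta pathway list, 8 of 21 measured members rose and 1 fell (8 and 2 adjusted over the list alone). Rises included BMPER (2.68 ± 0.21) and BMP2 (2.62 ± 0.24) (camera adjusted p = 0.000593, and adjusted p = 0.206 with an estimated correlation). A further 3 lists were called, and each lost its call without 1 array. The mesoderm and heart list (5 up and 1 down of 18, 6 up and 1 down adjusted over the list alone) was called with camera adjusted p = 0.00391, 0.0899 without ES replicate 1 and adjusted p = 0.377 with an estimated correlation. The FGF and ERK pathway list (5 down of 17, 1 up and 8 down adjusted over the list alone), with falls of FGF2 (-2.04 ± 0.28) and the ERK target ETV4 (-1.77 ± 0.21), was called with camera adjusted p = 0.0148, 0.252 without ES replicate 2 and adjusted p = 0.492 with an estimated correlation. In the cell cycle list, limma called 1 of 22 lower and 0 adjusted over the list alone (9 at unadjusted p under 0.05). That gene, CCNB1, lost its call without either ES array, either IVDS2 array or either IVDS3 array (adjusted p of 0.0568 to 0.207). The list had camera adjusted p = 0.00682, 0.218 without ES replicate 1 and adjusted p = 0.676 with an estimated correlation. Without IVDS2 replicate 2, the members that rose numbered 2 for cholangiocyte and 5 for the BMP and TGF-beta pathway, and without ES replicate 2 or IVDS2 replicate 2 they numbered 3 for mesoderm and heart. Those of the FGF and ERK pathway that fell numbered 3 without IVDS2 replicate 1 and 11 without ES replicate 1.

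The hepatoblast and mature hepatocyte lists were not called at this stage with all arrays. Of their 40 and 48 genes, 32 and 22 were measured, without ALB, TTR and HNF4A. In the hepatoblast and fetal liver list, 3 of 32 measured members rose and 1 fell (3 and 1 adjusted over the list alone, median 0.05, camera adjusted p = 0.178). Without IVDS2 replicate 1, 5 members rose. In the mature hepatocyte metabolism list 3 of 22 fell (3 adjusted over the list alone), and its camera adjusted p was 0.129, but 0.0437 without ES replicate 1, where it was called lower. The log2 fold change was 0.05 ± 0.12 for AFP, -0.04 ± 0.12 for SERPINA1 and 0.17 ± 0.15 for APOB, none of them called. Of the 16 measured landmark genes, 1 rose and 2 fell. The early endoderm genes SOX17 (-0.27 ± 0.31), FOXA2 (-0.12 ± 0.12) and GATA4 (-0.30 ± 0.14) were not called, and GATA6 (1.81 ± 0.56, adjusted p = 0.0684) was called without ES replicate 1 (adjusted p = 0.043) or either IVDS2-C array (adjusted p = 0.0277). FGB, a fibrinogen chain, had 1.57 ± 0.85 (adjusted p = 0.282), with values of -0.25 and 3.05 on the 2 IVDS2 arrays, and it was called without IVDS2 replicate 1 (adjusted p = 0.00535). The interferon response list (median -0.01, camera adjusted p = 0.872) and the fibroblast list (median -0.05, mean 0.03, camera adjusted p = 0.631) were not called either.

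**Figure D2:**
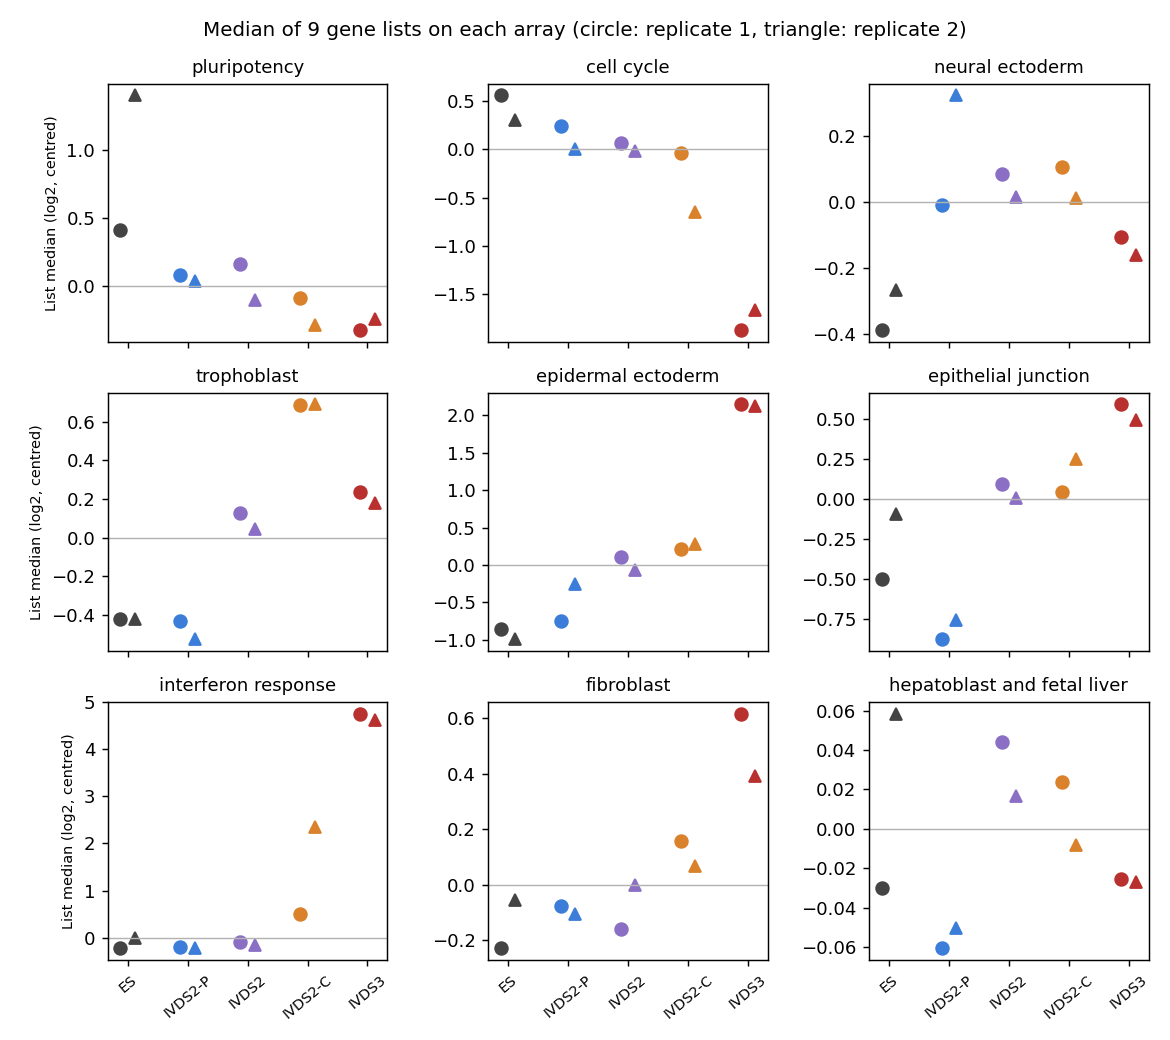
Each panel shows, for 1 gene list, the median over its measured members on each of the 10 arrays (log2, relative to the median array), with circles for replicate 1, triangles for replicate 2 and a scale of its own. The interferon response list reads 4.75 and 4.61 on the IVDS3 arrays, 0.50 and 2.35 on the IVDS2-C arrays, and between -0.22 and -0.01 on the other 6.

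By stage 3, 15 of 19 pluripotency genes and all 22 measured cell cycle genes had fallen, and all measured members of the epidermal and interferon response lists had risen (adjusted p = 0.434, 0.362, 0.119 and 0.362 with an estimated correlation). The mucosal keratin KRT4 rose by 8.56 ± 0.20 (SE) on the log2 scale (379-fold, n = 2 arrays per group, adjusted p = 3.64e-08). Other rises were GABRP (8.19 ± 0.23), CLDN8 (7.56 ± 0.39), a tight junction claudin, the calcium-binding protein S100A9 (7.50 ± 0.22), the matrix protein TGFBI (7.41 ± 0.32), and the interferon-induced IFIT1 (7.96 ± 0.71) and IFI27 (7.48 ± 0.61), with adjusted p of at most 3.05e-05. POU5F1 fell by 7.60 ± 0.79 (194-fold, adjusted p = 6.84e-05). The secreted WNT antagonists SFRP1 (-6.20 ± 0.38) and SFRP2 (-5.36 ± 0.29), DPPA4 (-5.93 ± 0.53), SPP1 (-5.82 ± 0.78), DNMT3B (-5.25 ± 0.37), ARHGAP36 (-5.17 ± 0.68) and SALL4 (-4.73 ± 0.36) fell with it, with adjusted p of at most 0.000285. All these calls held whichever array was left out.

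All 14 measured members of the interferon response list rose, and all of them passed when adjusted over the list alone. The list median was 4.83, with 5.01 between the replicate 1 arrays and 4.63 between the replicate 2 arrays (camera adjusted p = 4.8e-10, and adjusted p = 0.362 with an estimated correlation). IFIT3, an antiviral effector, rose by 7.11 ± 0.63, beside IFIT1 and IFI27. All 9 measured members of the epidermal ectoderm list rose as well, also adjusted over the list alone, among them the desmosomal cadherins DSG3 (6.04 ± 0.40) and DSC3 (3.20 ± 0.18), the epithelial 14-3-3 protein SFN (4.54 ± 0.31) and PERP (3.60 ± 0.25). Its median was 3.01, with 3.15 between the replicate 1 arrays and 3.11 between the replicate 2 arrays, and 4.54 with the most variable probe set of each gene (camera adjusted p = 2.96e-08, and adjusted p = 0.119 with an estimated correlation). In the epithelial junction list, 15 of 21 measured members rose and 3 fell (15 and 3 adjusted over the list alone). Rises included RAB25 (4.35 ± 0.28), KRT19 (2.96 ± 0.20), DSP (2.42 ± 0.14), the splicing regulator ESRP2 (2.06 ± 0.23) and CDH1 (1.16 ± 0.24) (camera adjusted p = 1.29e-05, and adjusted p = 0.434 with an estimated correlation). The trophoblast list had a median of 1.58, with 1.62 between the replicate 1 arrays and 1.52 between the replicate 2 arrays (camera adjusted p = 0.000414, and adjusted p = 0.176 with an estimated correlation). There, 9 of 17 measured members rose and 2 fell (9 and 2 adjusted over the list alone). It was led by VGLL1 (6.17 ± 0.29), ELF5 (5.53 ± 0.23), GATA3 (4.42 ± 0.33) and KRT7 (3.02 ± 0.34). In the neural crest list, 8 of 13 measured members rose and 1 fell (8 and 1 adjusted over the list alone), with MSX2 (3.26 ± 0.25), TFAP2B (3.09 ± 0.19) and TFAP2A (2.92 ± 0.23) leading (camera adjusted p = 0.00211, and adjusted p = 0.327 with an estimated correlation).

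All 22 measured cell cycle genes fell, also when adjusted over the list alone. The median was -2.34, with -2.60 between the replicate 1 arrays and -2.09 between the replicate 2 arrays (camera adjusted p = 6.39e-10, and adjusted p = 0.362 with an estimated correlation). The replication licensing genes MCM3 (-3.33 ± 0.23), MCM2 (-2.90 ± 0.23) and CDC6 (-3.20 ± 0.28) and the mitotic cyclin CCNB1 (-2.92 ± 0.24) led the list, while the cell cycle inhibitor CDKN1A rose by 4.03 ± 0.21. CDKN1A belongs to the stress and immediate early list, in which 6 of 15 measured members rose (6 adjusted over the list alone) and the other 9 were not called (camera adjusted p = 0.0024, and adjusted p = 0.434 with an estimated correlation). The median of that list was 1.04, and 0.50 without ES replicate 1, where 3 members rose, as without IVDS3 replicate 1, against 10 without ES replicate 2. In the pluripotency list, 2 of 19 measured members rose and 15 fell (2 and 15 adjusted over the list alone). Its median was -1.92, with -1.31 between the replicate 1 arrays and -2.54 between the replicate 2 arrays (camera adjusted p = 0.000599, and adjusted p = 0.434 with an estimated correlation). SOX2 fell by 3.16 ± 0.21, whereas NANOG rose by 1.48 ± 0.19 (adjusted p = 0.00026), a call that held whichever array was left out. In the FGF and ERK pathway list, 1 of 17 measured members rose and 10 fell (1 and 10 adjusted over the list alone). Falls included FGF2 (-3.93 ± 0.28) and ETV1 (-2.83 ± 0.21) (camera adjusted p = 0.00467, and adjusted p = 0.434 with an estimated correlation).

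Fibroblast genes rose unevenly. In the fibroblast list, 14 of 26 measured members rose and 4 fell (14 and 4 adjusted over the list alone), with a median of 0.74, or 0.97 between the replicate 1 arrays and 0.78 between the replicate 2 arrays (camera adjusted p = 0.000294, and adjusted p = 0.282 with an estimated correlation). The proteoglycans LUM (5.48 ± 0.21) and DCN (4.57 ± 0.16) rose most, followed by COL1A2 (2.91 ± 0.16) and FN1 (2.72 ± 0.25). COL1A1, the partner chain of COL1A2 in type I collagen, had -0.74 ± 0.24 (adjusted p = 0.0306), a call lost without ES replicate 1 (adjusted p = 0.113), ES replicate 2 (adjusted p = 0.0649), IVDS3 replicate 1 (adjusted p = 0.0516) or IVDS3 replicate 2 (adjusted p = 0.167). VIM was not called (0.37 ± 0.29), except without ES replicate 1 (adjusted p = 0.0163). In the retinoic acid and HOX list, 11 of 19 measured members rose and 1 fell (11 and 1 adjusted over the list alone). Rises included MEIS1 (4.07 ± 0.30), MEIS2 (2.79 ± 0.34), HOXA5 (1.83 ± 0.15) and HOXA3 (1.74 ± 0.15) (camera adjusted p = 0.00185, and adjusted p = 0.176 with an estimated correlation).

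Liver genes moved in both directions, and 52 of 377 viral probe sets fell too, so small falls need not be liver-specific. In the hepatoblast and fetal liver list, 6 of 32 measured members rose and 7 fell (6 and 7 adjusted over the list alone), with a median of -0.12, a mean of 0.15 and an upward camera statistic that was not called (adjusted p = 0.717). Without IVDS3 replicate 1, 4 members fell. The fetal liver marker AFP fell by 0.64 ± 0.12 (adjusted p = 0.0022), and SERPINA1 was not called (0.15 ± 0.12). APOA1 had -1.84 ± 0.55 (adjusted p = 0.0215), a call lost without ES replicate 1 (adjusted p = 0.135) or IVDS3 replicate 1 (adjusted p = 0.137). Of the 16 measured landmark genes, 2 rose and 6 fell. FOXA2 (-0.29 ± 0.12), GATA4 (-0.21 ± 0.14), GATA6 (0.60 ± 0.56) and the mesoderm gene TBXT (-0.19 ± 0.12) were not called. A further 5 liver-related genes singled out after their values were seen rose whichever array was left out. They were CEBPA (3.84 ± 0.17), a transcription factor of hepatocytes and other epithelia, DLK1 (1.83 ± 0.36), AMBP (1.76 ± 0.20), the drug-metabolising CYP3A4 (3.76 ± 0.16) and the complement regulator CFI (3.35 ± 0.14), with adjusted p of at most 0.00256. FOXA3, an endoderm transcription factor also singled out afterwards, fell by 3.16 ± 0.27 (adjusted p = 2.4e-05). RBP4 (-0.50 ± 0.11, adjusted p = 0.00388) and APOM (-0.54 ± 0.13, adjusted p = 0.00618), chosen in the same way, fell too. These 3 falls were called whichever array was left out.

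The other lists were not called in IVDS3 against ES cells. The camera adjusted p was 0.817 for mature hepatocyte metabolism (4 up and 5 down of 22, 4 up and 5 down adjusted over the list alone), 0.177 for lipoprotein and lipid transport (1 up and 7 down of 17, 1 up and 7 down adjusted over the list alone), and 0.383 for coagulation and complement (6 up and 3 down of 24, 6 up and 3 down adjusted over the list alone). It was 0.924 for definitive endoderm (5 up and 5 down of 19, 5 up and 5 down adjusted over the list alone), 0.286 for primitive streak and mesendoderm, 0.863 for visceral endoderm and yolk sac, 0.286 for pancreas and intestine, and 0.075 for cholangiocyte. It was 0.216 for neural ectoderm, 0.701 for mesoderm and heart, 0.0931 for endothelial, 0.393 for blood and macrophage, 0.766 for smooth muscle and myofibroblast, and 0.337 for EMT regulators. It was 0.177 for the WNT pathway, 0.216 for the BMP and TGF-beta pathway, 0.0766 for hypoxia and glycolysis (0.0496 without IVDS3 replicate 2), and 0.0677 for cholesterol synthesis (0.0412 without ES replicate 2, 0.0291 without IVDS3 replicate 1 and 0.0451 with the most variable probe set of each gene). Median and mean had opposite signs for mature hepatocyte metabolism (-0.08 and 0.01), smooth muscle and myofibroblast (-0.12 and 0.00), definitive endoderm (-0.21 and 0.13), coagulation and complement (-0.06 and 0.33) and blood and macrophage (-0.01 and 0.61). The last 2 medians were 0.00 and 0.05 with each array centred on its median.

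In the central foci of stage 2 colonies, 9 of 21 members of the epithelial junction list, 11 of 19 of the neural ectoderm list and 7 of 14 of the interferon response list rose over ES cells (adjusted p = 0.336, 0.335 and 0.372 with an estimated correlation). GABRP (6.47 ± 0.23 (SE), 88.9-fold, n = 2 arrays per group, adjusted p = 7.22e-06) and HAPLN1 (6.42 ± 0.27) rose most. Further rises were in the scavenger receptor COLEC12 (5.57 ± 0.60), the basal epithelial factor BNC1 (5.27 ± 0.30), DENND1B (5.16 ± 0.30), KANK4 (5.14 ± 0.28) and IFIT1 (5.24 ± 0.71), with adjusted p of at most 0.000908. The largest falls included ARHGAP36 (-5.34 ± 0.68), POU5F1 (-5.08 ± 0.79), the phosphoprotein SPP1 (-4.82 ± 0.78), ITM2A (-4.45 ± 0.34), SFRP1 (-4.36 ± 0.38), DPPA4 (-4.19 ± 0.53), GPR176 (-3.99 ± 0.27) and RGS20 (-3.84 ± 0.28), with adjusted p of at most 0.00219.

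In the trophoblast list, 12 of 17 measured members rose (12 adjusted over the list alone) and the other 5 were not called. Those that rose included GATA3 (4.95 ± 0.33), VGLL1 (4.92 ± 0.29) and TP63 (3.20 ± 0.14). The median was 1.49, with 1.49 between the replicate 1 arrays and 1.06 between the replicate 2 arrays (camera adjusted p = 2.69e-07, and adjusted p = 0.114 with an estimated correlation). In the epidermal ectoderm list, 6 of 9 measured members rose (7 adjusted over the list alone) and the other 3 were not called, with SFN (2.52 ± 0.31) and DSG3 (2.39 ± 0.40) rising beside TP63. Its median was 2.36, with 1.66 between the replicate 1 arrays and 2.65 between the replicate 2 arrays (camera adjusted p = 6.53e-06, and adjusted p = 0.13 with an estimated correlation). In the neural ectoderm list, 11 of 19 measured members rose and 2 fell (11 and 3 adjusted over the list alone). Rises included the neuronal STMN2 (4.30 ± 0.60) and ELAVL4 (2.94 ± 0.30) as well as PAX6 (3.70 ± 0.48) and LMX1A (2.62 ± 0.22) (camera adjusted p = 0.00118, and adjusted p = 0.335 with an estimated correlation). Without IVDS2-C replicate 2, 7 of its members rose. In the epithelial junction list, 9 of 21 measured members rose (12 adjusted over the list alone) and the other 12 were not called, with RAB25 (2.51 ± 0.28), CLDN3 (1.93 ± 0.35) and CLDN7 (1.86 ± 0.30) rising (camera adjusted p = 6e-06, and adjusted p = 0.336 with an estimated correlation). In the BMP and TGF-beta pathway list, 10 of 21 measured members rose and 2 fell (11 and 3 adjusted over the list alone). Rises included MSX2 (4.80 ± 0.25), TGFBI (4.52 ± 0.32) and BMP2 (2.00 ± 0.24) (camera adjusted p = 6.94e-05, and adjusted p = 0.164 with an estimated correlation). In the cholangiocyte list, 6 of 13 measured members rose and 1 fell (7 and 1 adjusted over the list alone). Rises included SOX9 (2.47 ± 0.22), KRT7 (2.46 ± 0.34) and ANXA4 (1.90 ± 0.19) (camera adjusted p = 0.00117, and adjusted p = 0.248 with an estimated correlation).

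In the interferon response list, 7 of 14 measured members rose (11 adjusted over the list alone) and the other 7 were not called. The median was 1.50, but 0.61 between the replicate 1 arrays and 2.40 between the replicate 2 arrays, and it was 0.57 without IVDS2-C replicate 2 and 2.43 without IVDS2-C replicate 1 (camera adjusted p = 1.22e-05, and adjusted p = 0.372 with an estimated correlation). The gene IFIT3 rose by 4.61 ± 0.63 and CXCL10, a chemokine, by 4.05 ± 0.66. In the stress and immediate early list, 7 of 15 measured members rose (7 adjusted over the list alone) and the other 8 were not called. Rises included the stress factor DDIT3 (2.64 ± 0.43) and CDKN1A (2.18 ± 0.21) (camera adjusted p = 0.000168, and adjusted p = 0.335 with an estimated correlation). Without ES replicate 1 or IVDS2-C replicate 2, 3 of its members rose. In the fibroblast list, 9 of 26 measured members rose and 5 fell (11 and 5 adjusted over the list alone). Rises included FN1 (2.46 ± 0.25), COL1A2 (2.36 ± 0.16) and LUM (2.31 ± 0.21) (camera adjusted p = 0.0114, and adjusted p = 0.335 with an estimated correlation). Without ES replicate 2, IVDS2-C replicate 2 or either IVDS3 array, 2 of its members fell, and 3 without IVDS2-C replicate 1 or either IVDS2 array. In the retinoic acid and HOX list, 7 of 19 measured members rose (7 adjusted over the list alone) and the other 12 were not called. Rises included MEIS1 (3.30 ± 0.30), MEIS2 (2.35 ± 0.34) and CRABP1 (2.28 ± 0.40) (camera adjusted p = 0.00685, and adjusted p = 0.164 with an estimated correlation).

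In the pluripotency list, 1 of 19 measured members rose and 12 fell (1 and 14 adjusted over the list alone), and in the cell cycle list, 17 of 22 measured members fell (21 adjusted over the list alone) and the other 5 were not called. The pluripotency median was -1.23, and -0.81 without ES replicate 2 (camera adjusted p = 3.18e-05, and adjusted p = 0.335 with an estimated correlation). DNMT3B fell by 3.83 and SOX2 by 2.12, while NANOG rose by 1.30 ± 0.19 (adjusted p = 0.00151). The cell cycle median was -0.84, and -0.56 without IVDS2-C replicate 2 (camera adjusted p = 4.73e-06, and adjusted p = 0.372 with an estimated correlation), with falls of CDC6 (-1.59 ± 0.28) and MCM3 (-1.44 ± 0.23). Without IVDS2-C replicate 2, 7 members of the cell cycle list fell (11 without ES replicate 1), and 5 of the FGF and ERK pathway list. Calls for the neural crest list (5 up and 2 down of 13, 6 up and 4 down adjusted over the list alone, camera adjusted p = 0.0151, 0.0951 without ES replicate 1, adjusted p = 0.335 with an estimated correlation), the mesoderm and heart list (6 up and 2 down of 18, 6 up and 3 down adjusted over the list alone, camera adjusted p = 0.0248, 0.112 without ES replicate 1, adjusted p = 0.389 with an estimated correlation) and the FGF and ERK pathway list (1 up and 9 down of 17, 1 up and 10 down adjusted over the list alone, camera adjusted p = 0.0136, 0.101 without ES replicate 2, adjusted p = 0.389 with an estimated correlation) were each lost without 1 array. The upward neural crest call went with a mean of 1.09 and a median of -0.06. The sign of that median was not stable. It was 0.07 without ES replicate 1, 0.16 without ES replicate 2, 0.01 without IVDS2-C replicate 1 and 0.52 with the most variable probe set of each gene. In the hepatoblast and fetal liver list, 7 of 32 measured members rose and 2 fell (6 and 2 adjusted over the list alone), and it was not called (median -0.04, 0.01 with each array centred on its median, mean 0.11, camera adjusted p = 0.33). Without ES replicate 1, ES replicate 2 or IVDS2-C replicate 2, 4 members rose. Mature hepatocyte metabolism (1 up and 4 down of 22, 1 up and 4 down adjusted over the list alone, camera adjusted p = 0.128) was called lower only without IVDS2-C replicate 2 (0.0481).

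In the colony periphery, 10 of 19 members of the neural ectoderm list rose over ES cells and 6 of 19 of the pluripotency list fell (adjusted p = 0.475 with an estimated correlation for each). Among its largest rises were those of the scavenger receptor COLEC12 (5.63 ± 0.60 (SE), 49.5-fold, n = 2 arrays per group, adjusted p = 0.00163), HAPLN1 (4.75 ± 0.27), angiotensinogen, encoded by AGT (4.40 ± 0.29), MMRN1 (4.18 ± 0.63), NR2F2 (4.06 ± 0.31), DENND1B (3.80 ± 0.30) and PAX6 (3.67 ± 0.48), with adjusted p of at most 0.00438. ITM2A (-3.71 ± 0.34), MGAT4C (-3.28 ± 0.22) and the tight junction gene CLDN10 (-2.87 ± 0.17) were among the largest falls, with ITCH (-2.46 ± 0.23) and JAZF1 (-2.37 ± 0.30), and adjusted p of at most 0.00265. ARHGAP36 (-2.98 ± 0.68) fell in a call lost without ES replicate 1 (adjusted p = 0.0716), ES replicate 2 (0.0821) or IVDS2-P replicate 2 (0.116) and with only the 4 arrays compared (0.0502), and GALNT1 (-2.39 ± 0.44) in one lost without ES replicate 2 (0.0802) or IVDS2-P replicate 2 (0.0821). In the neural ectoderm list, 10 of 19 measured members rose (11 up and 1 down adjusted over the list alone). Rises included EMX2 (3.05 ± 0.32), LMX1A (2.93 ± 0.22) and PAX3 (2.77 ± 0.20) beside PAX6. Its median was 0.46, with 0.50 between the replicate 1 arrays and 0.55 between the replicate 2 arrays, and 0.89 with the most variable probe set of each gene (camera adjusted p = 2.06e-06, and adjusted p = 0.475 with an estimated correlation). In the pluripotency list, 1 of 19 measured members rose and 6 fell (1 and 12 adjusted over the list alone), with a fall of NR5A2 (-1.96 ± 0.24). Its median was -0.64, and -1.08 without ES replicate 1 (camera adjusted p = 0.000374, and adjusted p = 0.475 with an estimated correlation). POU5F1 (-1.66 ± 0.79, adjusted p = 0.203) was called only without IVDS2-C replicate 1 or IVDS2-C replicate 2 (adjusted p = 0.0411 for each) and with only the 4 arrays compared (adjusted p = 0.0162), and SOX2 was not called (-0.64 ± 0.21, adjusted p = 0.0859).

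These were the 2 lists whose call held whichever array was left out, although single arrays moved their counts. The neural ectoderm members that rose numbered 5 without IVDS2-P replicate 2 and 6 without ES replicate 2. The pluripotency members that fell numbered 3 without ES replicate 2 or either IVDS2-P array. Of single genes, MSX2 (3.52 ± 0.25), MSX1 (3.08 ± 0.23), BMP2 (2.17 ± 0.24) and TGFBI (2.37 ± 0.32) rose, and the smooth muscle gene CNN1 (-2.12 ± 0.29), the canalicular transporter ABCC2 (-1.94 ± 0.16) and ETV4 (-1.66 ± 0.21) fell, each called whichever array was left out. The other 9 lists had camera adjusted p between 0.0291 and 0.0488 and lost their call without at least 1 array. Without ES replicate 1 the p was 0.152 for the BMP and TGF-beta pathway (6 up and 1 down of 21, 6 up and 2 down adjusted over the list alone), 0.152 for neural crest (6 up and 1 down of 13, 6 up and 4 down adjusted over the list alone), 0.151 for cholesterol synthesis (2 up of 16, 3 up adjusted over the list alone), 0.0766 for smooth muscle and myofibroblast (3 down of 13, 5 down adjusted over the list alone), 0.0778 for EMT regulators (6 up of 13, 6 up and 1 down adjusted over the list alone), 0.0509 for mature hepatocyte metabolism (2 down of 22, 2 down adjusted over the list alone) and 0.416 for cell cycle. Without ES replicate 2 it was 0.341 for the FGF and ERK pathway (4 down of 17, 2 up and 5 down adjusted over the list alone), 0.157 for mature hepatocyte metabolism and 0.341 for pancreas and intestine. Without IVDS2-P replicate 1 it was 0.108 for the FGF and ERK pathway, 0.108 for cholesterol synthesis and 0.191 for smooth muscle. Without IVDS2-P replicate 2 it was 0.16 for cell cycle, 0.138 for mature hepatocyte metabolism and 0.108 for pancreas and intestine. Without IVDS2 replicate 1 or 2 it was 0.0518 for mature hepatocyte metabolism and for pancreas and intestine. It was 0.0551 for the latter without IVDS2-C replicate 1 or 2. In the cell cycle and the pancreas and intestine lists, limma called 0 of 22 and 0 of 12 members lower (5 and 3 at unadjusted p under 0.05). The EMT regulators that rose numbered 2 without IVDS2-P replicate 2 and 3 without ES replicate 2, IVDS2-P replicate 1 or either IVDS3 array. Smooth muscle falls numbered 1 without IVDS2-P replicate 2 and 5 without ES replicate 1. FGF and ERK pathway falls numbered 1 without IVDS2-P replicate 2, 2 without ES replicate 2, IVDS2-P replicate 1 or either IVDS3 array, and 9 without ES replicate 1. Mature hepatocyte falls numbered 1 without either IVDS2-P array and 5 without ES replicate 1. Cholesterol synthesis rises numbered 4 without ES replicate 1, 1 without either IVDS2-P array and, in limma, 0 without ES replicate 2 (5 at unadjusted p under 0.05). With the most variable probe set of each gene the p was 0.0696 for mature hepatocyte metabolism, 0.0827 for smooth muscle and myofibroblast, and 0.0816 for the FGF and ERK pathway. The BMP and TGF-beta test and mean (0.62) pointed up, while the median (-0.02) had no stable sign. It was 0.09 without ES replicate 1, 0.37 without ES replicate 2, and 0.04 and 0.06 without IVDS2-P replicate 1 and 2. The neural crest median (0.15) was -0.08 without ES replicate 1 and 0.39 without ES replicate 2. With an estimated correlation the adjusted p of these lists was 0.475 to 0.661.

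**Figure D3:**
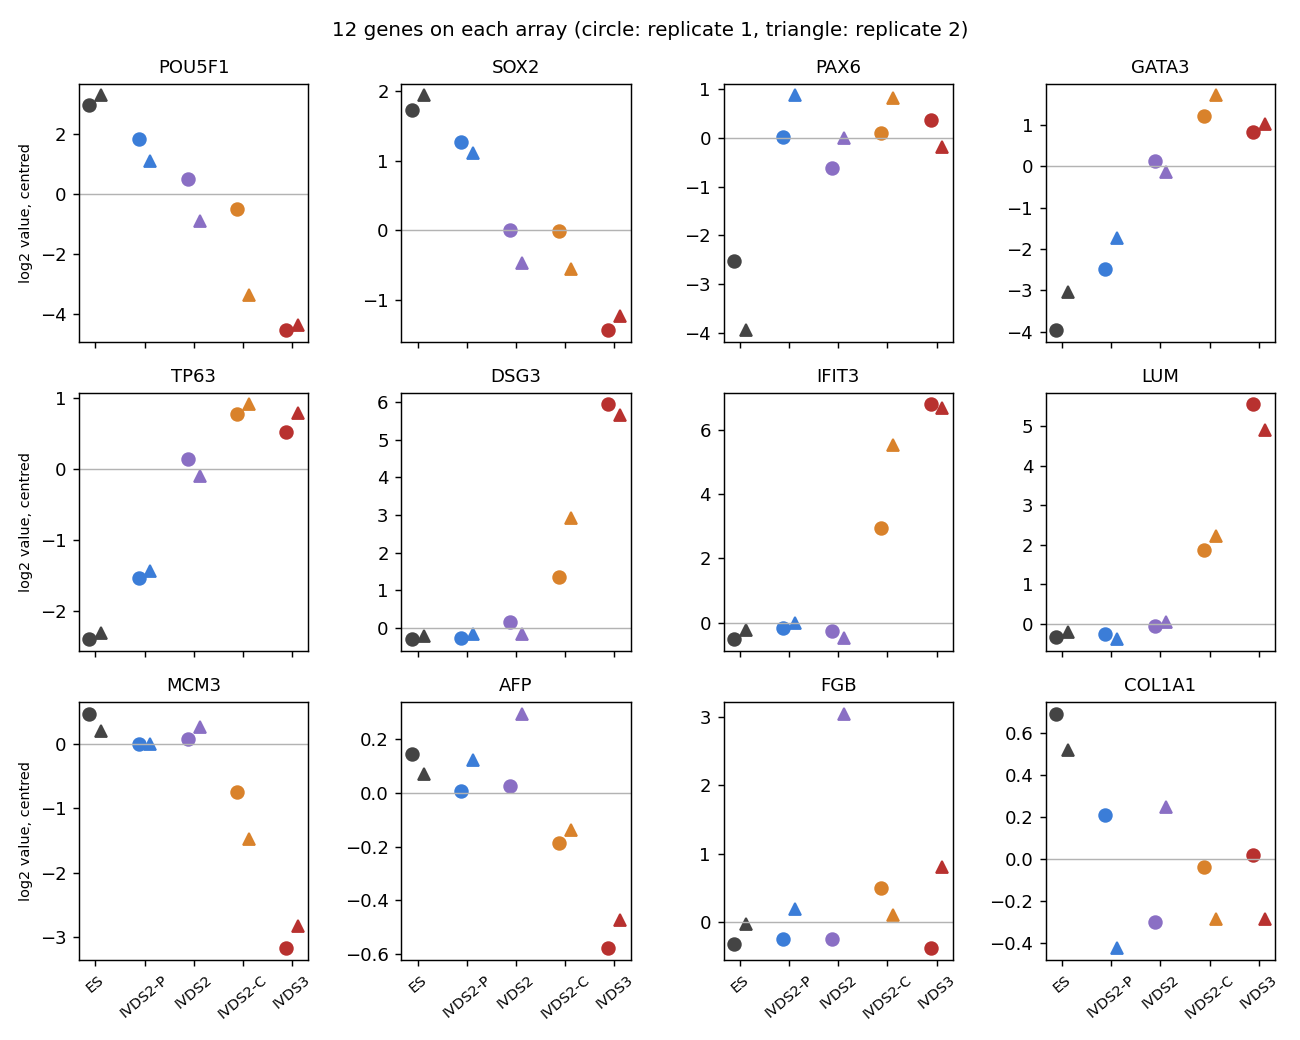
Values of 12 genes on each of the 10 arrays (log2, relative to the median array), with circles for replicate 1 and triangles for replicate 2. POU5F1 and SOX2 read lowest on the IVDS3 arrays, where DSG3, IFIT3 and LUM read highest, and FGB reads 3.05 on IVDS2 replicate 2 and at most 0.80 on the other arrays.

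Within stage 2 colonies, 11 of 17 members of the trophoblast list, 5 of 9 of the epidermal list, 15 of 21 of the epithelial junction list and 7 of 14 of the interferon response list were higher in the centre than in the periphery. With an estimated correlation only the first list was called (adjusted p = 0.038, 0.079, 0.283 and 0.33). IFIT1 (4.84 ± 0.71 (SE), 28.6-fold, n = 2 arrays per group, adjusted p = 0.00449), GABRP (4.69 ± 0.23), BNC1 (4.68 ± 0.30), IFIT3 (4.33 ± 0.63) and PLAC8 (4.06 ± 0.20) were among the largest rises and were called whichever array was left out, with adjusted p of at most 0.00449. With only the 4 arrays compared, the calls for IFIT1 (adjusted p = 0.0544) and IFIT3 (adjusted p = 0.0532) were lost. The transcription factor TWIST1 (-2.91 ± 0.35), SFRP1 (-2.89 ± 0.38), NPTX2 (-2.88 ± 0.34), RGS20 (-2.87 ± 0.28) and SFRP2 (-2.64 ± 0.29) were lower in the centre, with adjusted p of at most 0.00277. The xenobiotic-metabolising CYP1A1 (4.23 ± 0.67) rose in a call lost without IVDS2-P replicate 1 (adjusted p = 0.0565) and with only the 4 arrays compared (0.0539). OTUD3 (-2.55 ± 0.53) fell in a call lost without IVDS2-C replicate 2 (adjusted p = 0.147), IVDS2-P replicate 1 (0.112) or IVDS2-P replicate 2 (0.0859). SPP1 had -2.93 ± 0.78 (adjusted p = 0.0488), lost without IVDS2 replicate 1 or 2 (0.07 each), IVDS2-C replicate 2 (0.35), IVDS2-P replicate 1 (0.253) or 2 (0.0789), or IVDS3 replicate 1 or 2 (0.0763 each), with each array centred on its median (0.0527) and with only the 4 arrays compared (0.0901). In the trophoblast list, 11 of 17 measured members rose (13 adjusted over the list alone) and the other 6 were not called. Its median was 1.13, with 1.37 between the replicate 1 arrays and 0.95 between the replicate 2 arrays, and it was the 1 list still called with an estimated correlation (camera adjusted p = 2.63e-12, and adjusted p = 0.038 with an estimated correlation). GATA3 (3.57 ± 0.33), VGLL1 (3.28 ± 0.29), KRT7 (2.99 ± 0.34) and IGFBP3 (2.85 ± 0.33) rose most in it. In the epithelial junction list, 15 of 21 measured members rose (18 up and 1 down adjusted over the list alone), with RAB25 (2.26 ± 0.28), CLDN7 (2.04 ± 0.30) and ESRP2 (1.55 ± 0.23) rising. Its median was 1.06, with 0.93 between the replicate 1 arrays and 1.07 between the replicate 2 arrays (camera adjusted p = 1.16e-12, and adjusted p = 0.283 with an estimated correlation). Without IVDS2-P replicate 1, 7 trophoblast and 9 junction members rose, and 9 junction members without IVDS2-C replicate 2.

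In the epidermal ectoderm list, 5 of 9 measured members rose (6 adjusted over the list alone) and the other 4 were not called, with SFN (2.73 ± 0.31), PERP (2.36 ± 0.25) and TP63 (2.33 ± 0.14) rising. Its median was 1.13, with 1.25 between the replicate 1 arrays and 1.02 between the replicate 2 arrays (camera adjusted p = 2.09e-07, and adjusted p = 0.079 with an estimated correlation). In the interferon response list, 7 of 14 measured members rose (11 adjusted over the list alone) and the other 7 were not called. Its median was 1.56, but 0.66 between the replicate 1 arrays and 2.61 between the replicate 2 arrays, and it was 0.67 without IVDS2-C replicate 2, 2.50 without IVDS2-C replicate 1 and 2.39 with the most variable probe set of each gene (camera adjusted p = 5.68e-09, and adjusted p = 0.33 with an estimated correlation). In the stress and immediate early list, 4 of 15 measured members rose (10 adjusted over the list alone) and the other 11 were not called. Rises included GADD45B (3.35 ± 0.47) and CDKN1A (1.62 ± 0.21) (camera adjusted p = 1.42e-06, and adjusted p = 0.283 with an estimated correlation). In the mesoderm and heart list, 6 of 18 measured members rose (8 adjusted over the list alone) and the other 12 were not called. It was led by the cardiac progenitor factor ISL1 (3.41 ± 0.25) (camera adjusted p = 4.48e-05, and adjusted p = 0.283 with an estimated correlation). In the smooth muscle and myofibroblast list, 6 of 13 measured members rose and 1 fell (7 and 1 adjusted over the list alone), with a rise of TPM2 (1.37 ± 0.20) (camera adjusted p = 0.000194, and adjusted p = 0.283 with an estimated correlation). In the cholangiocyte list, 5 of 13 measured members rose and 3 fell (6 and 3 adjusted over the list alone). Rises included ANXA4 (1.93 ± 0.19) and KRT19 (1.55 ± 0.20) (camera adjusted p = 0.00959, and adjusted p = 0.283 with an estimated correlation). Without IVDS2-P replicate 1, the members that rose numbered 3 for the epidermal list and 2 each for the interferon response, mesoderm and heart, stress and immediate early, and smooth muscle lists. Without IVDS2-C replicate 2 they numbered 3 for mesoderm and heart, 2 for stress and immediate early and 1 for smooth muscle. They numbered 11 for interferon response without IVDS2-C replicate 1 and 7 for stress and immediate early without either ES array.

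In the pluripotency list, 7 of 19 measured members fell (8 adjusted over the list alone) and the other 12 were not called, with SOX2 lower in the centre by 1.47 ± 0.21 (adjusted p = 0.00416). The list median was -0.24, and -0.37 without IVDS2-C replicate 1 (camera adjusted p = 0.0153, and adjusted p = 0.538 with an estimated correlation). Its members that fell numbered 3 without IVDS2-C replicate 2, 1 without IVDS2-P replicate 1, and 4 without IVDS2-P replicate 2 or either IVDS3 array. POU5F1 had -3.41 ± 0.79 (adjusted p = 0.0305), a call lost without IVDS2-C replicate 2 (adjusted p = 0.101), IVDS2-P replicate 1 (0.168), IVDS2-P replicate 2 (0.0852) or IVDS3 replicate 1 (0.0549) or 2 (0.0549) and with only the 4 arrays compared (0.0996). In the cell cycle list, 7 of 22 measured members fell (9 adjusted over the list alone) and the other 15 were not called (camera adjusted p = 1.55e-06, and adjusted p = 0.348 with an estimated correlation). Limma called 0 members lower without IVDS2-C replicate 2, IVDS2-P replicate 1 or IVDS2-P replicate 2 (8, 8 and 14 at unadjusted p under 0.05). The list median was -0.52, -0.80 without IVDS2-C replicate 1, -0.21 without IVDS2-C replicate 2 and -0.34 without IVDS2-P replicate 1. Calls for 4 lists were lost without single arrays. For the BMP and TGF-beta pathway (6 up and 2 down of 21, 7 up and 2 down adjusted over the list alone) the camera adjusted p was 0.0153, 0.0953 without IVDS2-C replicate 1 and 0.118 without IVDS2-P replicate 1 (adjusted p = 0.283 with an estimated correlation). For fibroblast (6 up and 4 down of 26, 8 up and 5 down adjusted over the list alone) it was 0.0301, 0.0549 without IVDS2-C replicate 1, 0.0572 without IVDS2-P replicate 1 and 0.0595 with the most variable probe set of each gene (adjusted p = 0.33 with an estimated correlation), although TIMP3 (3.58 ± 0.49), LUM (2.36 ± 0.21) and COL1A2 (2.05 ± 0.16) rose whichever array was left out.

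For the WNT pathway (1 up and 3 down of 21, 1 up and 5 down adjusted over the list alone) the centre was lower, with camera adjusted p = 0.0427, 0.0859 without ES replicate 1 or 2, 0.171 without IVDS2-P replicate 2 and 0.0656 with the most variable probe set of each gene (adjusted p = 0.33 with an estimated correlation). The receptor FZD7 fell by 1.69 ± 0.26, a call lost with only the 4 arrays compared (adjusted p = 0.0523). For neural crest (3 up and 1 down of 13, 3 up and 1 down adjusted over the list alone) the camera adjusted p was 0.0486, 0.0825 without ES replicate 1 or 2, 0.172 without IVDS2-C replicate 1, 0.282 without IVDS2-P replicate 1 and 0.0582 with each array centred on its median (adjusted p = 0.335 with an estimated correlation). Without IVDS2-C replicate 2 or IVDS2-P replicate 1, 1 of its members rose. The hepatoblast and fetal liver list did not separate the centre from the periphery. In it, 4 of 32 measured members rose and 1 fell (4 and 1 adjusted over the list alone) (median 0.08, camera adjusted p = 0.191, 1 rise without IVDS2-C replicate 2 or IVDS2-P replicate 1 and 2 rises without IVDS2-P replicate 2), and AFP was not called (-0.23 ± 0.12). Of the 16 measured landmark genes, 1 rose and 2 fell. Neural ectoderm was not called either (median -0.03, camera adjusted p = 0.619).

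The other arrays were placed on the axis that runs from the periphery, set to 0, to the centre, set to 1, over the 2582 probe sets that separate these parts. The IVDS2 arrays lay at 0.36 and 0.33 (mean 0.35 ± 0.02, SD, n = 2), between the 2 parts and nearer the periphery. The ES arrays lay at -0.12 and -0.07, beside the periphery arrays at -0.05 and 0.05, and the IVDS3 arrays lay beyond the centre at 1.28 and 1.31 (mean 1.30 ± 0.03, SD, n = 2). The centre arrays themselves lay at 0.84 and 1.16. When each centre or periphery array was left out in turn, the mean for IVDS2 ranged from 0.24 without IVDS2-C replicate 1 to 0.44 without IVDS2-P replicate 2, and that for IVDS3 from 1.16 without IVDS2-P replicate 2 to 1.38 without IVDS2-C replicate 2.

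**Figure D4:**
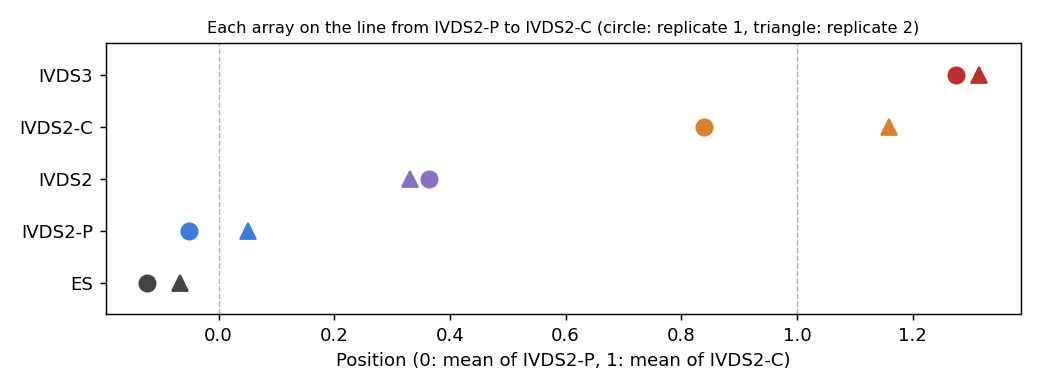
Each point is 1 array placed on the axis from the mean of the IVDS2-P arrays (0) to the mean of the IVDS2-C arrays (1), over 2582 probe sets, with circles for replicate 1 and triangles for replicate 2. The IVDS2 arrays lie at 0.36 and 0.33 and the IVDS3 arrays at 1.28 and 1.31.

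From stage 2 to stage 3, 7 of 9 members of the epidermal list, all 14 of the interferon response list and 13 of 26 of the fibroblast list rose, and all 22 of the cell cycle list fell (adjusted p = 0.253, 0.469, 0.269 and 0.522 with an estimated correlation). KRT4 (8.64 ± 0.20 (SE), 399-fold, n = 2 arrays per group, adjusted p = 3.69e-08), IFIT1 (7.84 ± 0.71), S100A9 (7.64 ± 0.22), CLDN8 (7.37 ± 0.39), IFIT3 (7.11 ± 0.63) and IFI44 (6.97 ± 0.15) were among the largest rises. The glycine-cleaving enzyme GLDC (-4.47 ± 0.36), LIX1 (-4.62 ± 0.45), POU5F1 (-4.25 ± 0.79), the cardiac actin ACTC1 (-4.12 ± 0.52), SFRP2 (-4.09 ± 0.29), the muscle actinin ACTN3 (-4.02 ± 0.38), SFRP1 (-3.92 ± 0.38) and SALL4 (-3.91 ± 0.36) were among the largest falls, with adjusted p of at most 0.0026. All 14 measured interferon response genes rose, also adjusted over the list alone. The list median was 5.01, with 5.09 between the replicate 1 arrays and 4.93 between the replicate 2 arrays (camera adjusted p = 4.14e-12, and adjusted p = 0.469 with an estimated correlation). All 22 measured cell cycle genes fell, also adjusted over the list alone, with a median of -1.80, or -2.09 between the replicate 1 arrays and -1.56 between the replicate 2 arrays (camera adjusted p = 1.06e-10, and adjusted p = 0.522 with an estimated correlation). Examples were MCM3 (-3.16 ± 0.23), CDC6 (-2.83 ± 0.28) and MCM5 (-2.72 ± 0.22). In the epidermal ectoderm list, 7 of 9 measured members rose and 1 fell (7 and 1 adjusted over the list alone), with DSG3 (5.80 ± 0.40), SFN (3.62 ± 0.31) and the cornified envelope protein IVL (2.82 ± 0.27) rising. Its median was 2.10, with 2.06 between the replicate 1 arrays and 2.18 between the replicate 2 arrays (camera adjusted p = 0.000247, and adjusted p = 0.253 with an estimated correlation).

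In the fibroblast list, 13 of 26 measured members rose and 2 fell (14 and 2 adjusted over the list alone). It was led by LUM (5.22 ± 0.21), DCN (4.35 ± 0.16) and the fibroblast activation protein FAP (2.26 ± 0.22) (median 0.69, camera adjusted p = 7.52e-05, and adjusted p = 0.269 with an estimated correlation). In the epithelial junction list, 11 of 21 measured members rose and 2 fell (11 and 3 adjusted over the list alone), with RAB25 (2.45 ± 0.28) and DSP (2.00 ± 0.14) rising (camera adjusted p = 0.0116, and adjusted p = 0.649 with an estimated correlation). Without IVDS3 replicate 1, 7 of its members rose. In the retinoic acid and HOX list, 9 of 19 measured members rose and 1 fell (10 and 1 adjusted over the list alone). Rises included CYP26A1 (2.98 ± 0.45), which degrades retinoic acid, MEIS1 (2.21 ± 0.30) and HOXA5 (1.75 ± 0.15) (camera adjusted p = 0.00441, and adjusted p = 0.253 with an estimated correlation). In the stress and immediate early list, 5 of 15 measured members rose (5 adjusted over the list alone) and the other 10 were not called. It was led by CDKN1A (3.67 ± 0.21) (camera adjusted p = 0.028, and adjusted p = 0.649 with an estimated correlation). The call for the list was lost without IVDS2 replicate 1 (camera adjusted p = 0.0936) and with the most variable probe set of each gene (0.0534), and 2 members rose without IVDS3 replicate 2 and 3 without IVDS2 replicate 1 or IVDS3 replicate 1. The FGF and ERK pathway list (7 down of 17, 7 down adjusted over the list alone) was not called (camera adjusted p = 0.0574), but it was called lower without either ES array (0.03), either IVDS2-C array (0.0409) or IVDS3 replicate 1 (0.0484) and with each array centred on its median (0.0398). Pluripotency (1 up and 8 down of 19, 1 up and 8 down adjusted over the list alone) was likewise not called (camera adjusted p = 0.0654), but was called lower without IVDS2 replicate 2 (0.0137), either IVDS2-C array (0.0343) or IVDS3 replicate 1 (0.0484) and with centred arrays (0.047). In the hepatoblast and fetal liver list, 3 of 32 measured members rose and 7 fell (3 and 6 adjusted over the list alone), and it was not called (median -0.17, camera adjusted p = 0.813). Without IVDS3 replicate 1, 2 members fell, and 4 without IVDS2 replicate 2. AFP fell by 0.69 ± 0.12 (adjusted p = 0.00196).

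The step from periphery to centre and the step from stage 2 to stage 3 were compared gene by gene, a comparison chosen after the data were seen. They share no array, although both take their spread from the same fit. Of the 744 genes higher in the centre, 526 were also higher in IVDS3 than in IVDS2, where 131 would be shared by independent sets (Fisher's exact test over 13191 genes, two-sided p = 3.93e-242). Of the 521 genes lower in the centre, 408 were also lower in IVDS3, against 116 (Fisher's exact test, two-sided p = 1.24e-171), and 37 and 12 genes moved in opposite directions, against 165 and 91.5. Genes are not independent of each other, so these p-values are too small. Single arrays moved the shared counts by more than 1.5 times. The shared rises numbered 243 without IVDS2-C replicate 2, 205 without IVDS2-P replicate 1 and 291 without IVDS2-P replicate 2. The shared falls numbered 44, 62 and 69 without those arrays, 648 without IVDS2-C replicate 1, 270 without IVDS2 replicate 1, and 182 and 175 without IVDS3 replicate 1 and 2.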

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

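The tests of explanations for the interferon rise and both tests that set fibroblast genes against epidermal genes were chosen after the results were seen. The poly-A signal below appeared in control probe sets that no comparison uses. The 36 poly-A spike-in probe sets, for RNAs added before labelling, were higher on the replicate 1 array than on the replicate 2 array of every group, by at least 1.03 (log2) and at most 1.58. Their medians were 0.40 to 0.93 on the replicate 1 arrays and -0.88 to -0.41 on the replicate 2 arrays, while those of the 27 spike-in probe sets added at hybridisation lay between -0.13 and 0.28. Labelling controls therefore split by replicate number in all 5 groups. The viral probe sets, which count among the tested probe sets but enter no gene or list result, had a median of 0.34 on ES replicate 2, against at most 0.0523 on the other 9 arrays, and the cause was not tested.

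In the interferon response list, 7 of 14 measured members rose in IVDS2-C against IVDS2-P and all 14 in IVDS3 against ES cells (adjusted p = 0.33 and 0.362 with an estimated correlation). A virus represented on the array would have raised viral probe sets, but their largest rise was 0.33 (log2), and limma called 0 of 377 higher in IVDS3 (0 at unadjusted p under 0.05). A labelling shift shared by a replicate number cancels between groups and was not tested, nor was a batch tied to group. Within-replicate medians were at least 4.63 in IVDS3, but 0.66 and 2.61 in IVDS2-C, leaving that size open. Carried-over fibroblast-like cells may contribute, since the fibroblast list rose in IVDS3 (median 0.74, adjusted p = 0.282 with an estimated correlation), but COL1A1 was lower (-0.74) and VIM was not called (0.37), while COL1A2 (2.91) and COL3A1 (0.97) were higher, so this could not be settled. An interferon response of the differentiating cells remains possible and was not tested.

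In the epidermal list, 4 of 9 measured members rose in IVDS2 and all 9 in IVDS3 (adjusted p = 0.156 and 0.119 with an estimated correlation), while the hepatoblast and fetal liver list was called in neither. Liver probe sets that stay at background could hide a rise: 50% of the hepatoblast list probe sets (28 of 56) varied more over the arrays than the 95th percentile of viral and reporter probe sets, against 18 of 18 epidermal ones, which does not settle it. Carried-over fibroblast-like cells are an unlikely source of the epidermal rise in IVDS2, where the fibroblast list had a median of -0.0502 against 0.92 for the epidermal list (exact two-sided rank-sum test over genes, p = 0.00228). In IVDS3 the medians were 0.74 and 3.01 (exact two-sided rank-sum test over genes, p = 0.000195), and since 14 of 26 fibroblast list members rose and 4 fell (adjusted p = 0.282 with an estimated correlation), a contribution of such cells could not be excluded. Genes are not independent, so these p-values are too small.

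Many probe sets were called lower against ES cells, and the higher values of ES replicate 2 at viral probe sets could go with a part of this, although their cause was not tested. Without that array, 10 viral probe sets were called lower in IVDS3 in place of 52, so most of those calls depended on it. The fall of the pluripotency list was not explained this way, since its median in IVDS3 was -1.30 without ES replicate 2 and -1.92 with it (adjusted p = 0.434 with an estimated correlation). A loss of pluripotency transcripts on differentiation would give such a fall, and it was not tested by other means.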

How the results depend on the processing

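The most variable probe set of each gene, the overlap between steps the within-replicate list medians and the counts of list and family members without single arrays were added as tests after the data were seen. No named gene and no list was called in the opposite direction under any alternative, but the balance of higher and lower probe sets and some list medians near 0 turned. When each array was left out in turn, the number of changed probe sets ranged from 1757 (without IVDS2 replicate 2) to 5648 for IVDS2 against ES cells, 12019 (without IVDS3 replicate 1) to 18083 for IVDS3, 4263 (without IVDS2-C replicate 2) to 10982 for IVDS2-C, and 818 (without IVDS2-P replicate 2) to 7423 for IVDS2-P. It ranged from 684 (without IVDS2-P replicate 1) to 3418 for IVDS2-C against IVDS2-P and from 7899 (without IVDS3 replicate 1) to 14517 for IVDS3 against IVDS2. The highest counts came without ES replicate 1, and for the last 2 comparisons the count was the same without ES replicate 2. The lists called numbered 11 to 12, 11 to 12, 13 to 18, 4 to 11, 11 to 14 and 6 to 10 in the same order of comparisons, with 4 without ES replicate 1 for IVDS2-P. The axis position ranged from 0.24 to 0.44 for IVDS2, 1.16 to 1.38 for IVDS3 and -0.12 to -0.07 for ES. Small counts of members called against the direction of their list also moved and are not listed. A group left with 1 array is assumed to vary like the others.

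Fitting only the 4 arrays compared, with fewer residual degrees of freedom, left 2115, 13242, 5248, 1514, 1685 and 13340 probe sets in the same order of comparisons. Of 404 named gene results, 370 then kept their call status, 31 lost a call and 3 gained one. With the correlation estimated per list, camera in limma called 0 lists for IVDS2, IVDS3, IVDS2-C and IVDS2-P against ES cells (5, 4, 5 and 2 at unadjusted p under 0.05), 1 for IVDS2-C against IVDS2-P and 0 for IVDS3 against IVDS2 (3 at unadjusted p under 0.05), and the cause was not tested. Leaving out IVDS2-P replicate 1 cost 38 named gene results their call, the most of any array. Of the 65 named genes called for IVDS2-C against IVDS2-P, 37 kept the call whichever array was left out. With centred arrays, 401 of 404 named gene results kept their call status and 3 lost the call, and of the list results 177 kept it, 2 gained it and 1 lost it. With the most variable probe set these were 169, 5 and 6. The replicate block gave 4279, 17183, 10090, 3826, 3090 and 13191 changed probe sets in the order of comparisons. For lists, it ended the calls of WNT pathway (0.055) and neural crest (0.0502) for IVDS2-C against IVDS2-P. It also ended those of mature hepatocyte metabolism (0.051) and pancreas and intestine (0.0558) for IVDS2-P against ES cells. The FGF and ERK pathway gained a call for IVDS3 against IVDS2 (0.0464). The probe set counts with the block are compared next. Correlations of replicate 1 minus replicate 2 between groups were -0.12 to 0.25 (median 0.11), so the numbers were not treated as pairs, although the poly-A spike-ins split by number. As the deposited values are centred, the steps named with the processing were not run. Nor could signal over background be read, so dim probe sets limit what can be called.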

Other observations

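The gene families and genes here were chosen for tests after the data were seen. In 66 two-sided Fisher's exact tests (11 families, 3 comparisons, rises and falls), adjusted together, several families were rich in rises in IVDS3 against ES cells: 15 of 30 keratins (1 fell, adjusted p = 0.00305), 9 of 11 S100A proteins (1 fell, adjusted p = 0.000969), 5 of 7 clade B serpins (adjusted p = 0.0245) and 8 of 16 claudins (3 fell, adjusted p = 0.0376). KRT1 (log2 fold change 5.72), KRT13 (3.45), S100A8 (6.40), SERPINB2 (6.80) and CLDN1 (4.64) were among them. Without ES replicate 1, 5 keratins and 5 claudins fell. The fall of 1 keratin was not called without ES replicate 2 or IVDS3 replicate 2, nor that of 1 S100A protein without either ES or either IVDS3 array. In the PARP family 7 of 12 rose and 3 fell (adjusted p = 0.0233 for the rises), with PARP14 (4.44) and PARP9 (3.66) among the rises and PARP1, PARP2 and PARP15 the falls, and 6 of 7 MCM helicase genes fell (adjusted p = 0.0147). Between IVDS2-C and IVDS2-P, 5 of 11 S100A proteins and 6 of 16 claudins were higher in the centre (adjusted p = 0.00187 for each), and 5 of 7 MCM helicase genes were lower (adjusted p = 0.000122). These depended on single arrays. In limma 0 MCM helicase genes were called lower without IVDS2-C replicate 2 (5 at unadjusted p under 0.05) or without IVDS2-P replicate 1 or 2 (6 at unadjusted p under 0.05 for each), and 3 without IVDS3 replicate 1 or 2. The S100A proteins numbered 3 without IVDS2-C replicate 2 or either IVDS2-P array (adjusted p of at most 0.0255). The claudins numbered 4 without IVDS2-C replicate 2 or IVDS2-P replicate 2 and 2 without IVDS2-P replicate 1, where the enrichment was not called (adjusted p = 0.138). The directions were the same with each array centred on its median. Family members are not independent, so these p-values are too small.

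Further genes had large changes in IVDS3 against ES cells. KLF5 rose by 6.06, LYZ by 4.98, the neuronal gene STMN2 by 5.67 and WNT3 by 3.28, while GAPDH fell by 1.97. Within colonies, KLF5 (3.81), the complement gene C5 (2.21) and CEBPA (1.16) were higher in the centre than in the periphery. FGG followed FGB, with -0.09 on IVDS2 replicate 1 and 1.59 on IVDS2 replicate 2.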
